A study of Mus musculus with 10 samples.

How the data were processed

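Lineage-negative, Kit-positive cells sorted from femoral bone marrow of 10 mice were measured by droplet single-cell RNA sequencing, with 1 library per mouse. Per the labels' protocols, libraries were made with 10x Genomics 3' chemistry, sequenced on a NovaSeq instrument and counted with Cell Ranger 7.1.0, with intronic reads included, against the mm10 reference (GRCm38). The deposited values are raw UMI (unique molecular identifier) counts per gene and cell barcode in cell-called matrices of 32285 genes. They held 49216 barcodes and 889862421 UMIs in total.

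Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Doublets were scored with Scrublet in scanpy (expected rate 0.06). The automatic score threshold marked under 0.5% of cells in 9 libraries, so, after the scores were seen, the highest-scoring cells were removed at 0.8% per 1000 barcodes. This left 36851 cells, from 2197 in treated DKO ERY 1 to 6108 in DKO ERY 1. The share of barcodes above the mitochondrial limit was 39.4% in Trp53KO and 31.4% in Bap1KO, and between 7.50% in DKO AML 2 and 17.2% in treated DKO ERY 2 in the other 8 libraries. Below the UMI or gene minimum were 28.0% of barcodes in treated DKO ERY 1, 25.3% in treated DKO ERY 2 and 2.53% to 18.0% in the rest.

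Cells of all libraries were clustered together in Python 3.11.15 with scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9 and leidenalg 0.10.2. Of 2500 variable genes, 2410 were used after mitochondrial, ribosomal, sex-linked and immune receptor genes, Malat1 and ribosomal RNA fragments were left out. From 30 principal components, a Harmony-style correction for library (50 clusters, theta 2, sigma 0.1, 10 iterations) and 15 nearest neighbours, Leiden clustering at resolution 1 gave 27 clusters. A cluster took the name of the class whose fixed marker list scored highest, if further conditions held. That class had to lead the next by 0.3, with at least 3 markers at 5 CPM (counts scaled to the library total) or more. The cluster's top 10 genes by fold had to hold at least as many markers of that class as of any other. Clusters of very low depth for their libraries also needed a marker of that class among those 10 genes. In all, 8 clusters stayed unnamed. Class names end in "like" because they rest on transcripts alone.

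UMIs were summed per gene over all kept cells of a library, and over the cells of a class where a library held at least 50 of them, so that the mouse is the replicate. All 10 libraries entered a single fit with 4 sets. These were the 3 libraries without both deletions (WT, Trp53KO and Bap1KO, 1 each, called the reference libraries), DKO ERY (3), DKO AML (2) and treated DKO ERY (2). The reference libraries differ in genotype, so their spread includes genotype differences. Genes were filtered with filterByExpr, scaled by TMM (trimmed mean of M-values; factors 0.897 to 1.13), and tested with edgeR 4.0.16 (robust quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values are scaled by the TMM-adjusted library size. Replicate libraries of 1 set differed by more than counting error, with a chi-square per degree of freedom of 38.5 (the treated pair) to 433 (the DKO AML pair).

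Shares of cells per class were compared with two-sided exact permutation tests over libraries. Neither 3 against 3 nor 2 against 3 libraries can give a p below 0.1. Shares of single libraries carry 95% exact Clopper-Pearson intervals, and ratios between single libraries carry exact conditional binomial intervals. Both cover counting error only. Trp53KO and Bap1KO have 1 library each and were compared with WT by ratios, as planned, and by an edgeR test chosen after the data were seen. That test fits all 10 libraries as 6 groups, which leaves 4 residual degrees of freedom, and assumes that the lone libraries vary like the replicated groups. For the planned comparison, the median log2 ratio of a gene list is given with its percentile among 10000 random lists of the same size matched on mean expression.

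The comparisons, tests, gene lists, marker lists and the rule for naming genes were fixed before the data were examined, as were most of the alternatives, and choices made later are named in the closing parts. Named genes were the 10 with the largest change in each direction (5 within a class) among those past the threshold with a mean of at least 50 CPM in 1 of the sets and no overlap between the sets' libraries. Mitochondrially encoded genes, the sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Kdm5d and Uty, immune receptor segments and unnamed gene models were left out of that rule. For Trp53KO and Bap1KO against WT, where no test was planned, the 10 largest ratios in each direction at 50 CPM or more were named. From each gene list, up to 4 members with the smallest adjusted p were added.

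There were 28 lists. They cover p53 targets, anti-apoptotic and pro-apoptotic BCL2 family members, BAP1 partners and polycomb, early and late erythroid genes, haem synthesis and iron, embryonic globins, stem cell genes, HoxA and Meis genes, and markers of neutrophil granules, monocytes, megakaryocytes, basophils and mast cells, B lineage, T and NK cells, macrophages, and stroma and endothelium. The rest cover S phase, G2/M phase, MYC and ribosome biogenesis, interferon response, MHC class II, immediate-early stress genes, cholesterol synthesis, glycolysis and hypoxia, the integrated stress response, and DNA damage repair. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the 27 lists testable in a comparison. Too few embryonic globin genes passed the filter for a test. An estimated correlation and fry stand beside camera. A list's score is the mean log2 CPM of its tested genes in a library, centred over libraries, and was added after the data were seen. The immediate-early score given is the one used as a term in the fits, scaled before the filter on low counts. Erythroid markers named the erythroid-like class and also make up much of the early and late erythroid lists, so the list and the class are not independent.

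The procedure was tested on simulated counts drawn from these libraries' means, with 100 genes changed 2-fold, 100 changed 4-fold and a short list changed by less. Over all kept cells, it recovered 50% of the 2-fold and 93% of the 4-fold genes for DKO ERY against the reference libraries. The recovered shares were 42% and 96% for DKO AML against them, 43% and 93% for DKO AML against DKO ERY, and 36% and 93% for treated against untreated DKO ERY. Within erythroid-like cells they were 26% and 94%, 16% and 87%, and 27% and 93% for the first 3 of these comparisons, and within granulocyte-monocyte-like cells 39% and 95% for DKO AML against the reference libraries. Over all kept cells, false calls were 3.9% (6 of 152), 7.9% (12 of 152), 3.5% (5 of 143) and 3.0% (4 of 134) of the genes called, in the same order. They were 11.7% (16 of 137), 6.4% (7 of 110) and 5.5% (7 of 128) within erythroid-like cells and 2.1% (3 of 140) within granulocyte-monocyte-like cells. False calls thus exceeded the 5% aimed at for DKO AML against the reference libraries over all kept cells and for each comparison within erythroid-like cells. Simulated genes varied independently, and the libraries of a set shared their means. The real reference libraries differ in genotype, so these shares need not hold for the real calls.

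Alternatives included DESeq2 1.42.0 (size factors and Wald test), library size without TMM, no filter on low counts, sex as a term, only the compared sets in the fit, WT as the sole reference, stricter cell filters (2000 UMIs, 1000 genes and 5% mitochondrial UMIs), doublets kept, haemoglobin genes left out, libraries thinned to equal depth, doubled clustering resolution, a class assigned to each cell by its own marker scores, and leaving out each library in turn. Gene coordinates are 1-based GRCm38 positions from GENCODE M21, which holds 32158 of the 32285 gene identifiers. Treated and untreated DKO ERY were not compared within erythroid-like cells, because treated libraries 1 and 2 held only 37 and 49 of them.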

Results

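Bone marrow progenitors (lineage-negative, Kit-positive) of 10 mice were profiled by single-cell RNA sequencing to compare the loss of Bap1, of Trp53 and of both. Bap1 encodes a nuclear deubiquitinase that acts on histones, and Trp53 encodes the tumour suppressor p53. Per the labels, 1 mouse was wild type (WT), 1 lacked Trp53 (Trp53KO), 1 lacked Bap1 (Bap1KO) and 7 lacked both (DKO). The DKO mice were labelled ERY (3 untreated and 2 given A-1155463, an inhibitor of the anti-apoptotic protein BCL-XL) or AML (2, untreated). The labels spell out neither term and give no dose or duration. Females gave 8 libraries, and DKO ERY 1 and treated DKO ERY 2 came from males.

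Total depth was 82286161 UMIs in WT, 86330317 in Trp53KO and 107959302 in Bap1KO. The DKO ERY libraries 1, 2 and 3 held 121279113, 76736728 and 79051394 UMIs, and the DKO AML libraries 1 and 2 held 73746052 and 151971318. Treated DKO ERY libraries 1 and 2 held 48258002 and 62244034. Kept cells had a median of 13510 UMIs in treated DKO ERY 1, the lowest, and 27167 in DKO AML 2, the highest.

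The targeted genes were detected in every library. Bap1 (ENSMUSG00000021901, chromosome 14, 31251450 to 31259944) was at 13.6 CPM in WT, 21.5 in Trp53KO, 19.04 in Bap1KO and 20.2 to 31.2 in the DKO libraries. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was at 104.8 CPM in WT, 82.5 in Trp53KO, 144.8 in Bap1KO and 54.6 to 108.5 in the DKO libraries. Counts near the 3' end can lie outside a deleted exon, and intronic reads were counted, so these levels check neither deletion. Bcl2l1, which encodes the drug target BCL-XL (chromosome 2, 152780668 to 152831728), was at 8.26 to 14.7 CPM, and Kit (chromosome 5, 75574916 to 75656722) at 72.6 to 119.5. None of the 4 genes passed the threshold in any of the 4 comparisons, and the lowest adjusted p (edgeR) was 0.0696, for Bap1 in DKO AML against the reference libraries.

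The sort held granulocyte-monocyte-like cells, HSC/MPP-like cells (stem cells and multipotent progenitors), erythroid-like, megakaryocyte-like, dendritic-like, basophil/mast/eosinophil-like, B-lineage-like and T/NK-like cells. Erythroid-like cells made up 2.37% of kept cells in WT (95% Clopper-Pearson interval 1.92% to 2.89%), 4.26% in Trp53KO (3.60% to 5.01%) and 4.81% in Bap1KO (4.15% to 5.55%). They made up 11.6% ± 2.13 (SD, n = 3) in DKO ERY, 4.69% ± 1.07 (n = 2) in DKO AML and 1.84% ± 0.219 (n = 2) in treated DKO ERY. Granulocyte-monocyte-like cells made up 55.4% in WT (53.8% to 56.9%), 32.1% in Trp53KO (30.5% to 33.7%) and 26.8% in Bap1KO (25.4% to 28.2%), against 38.5% ± 7.20 in DKO ERY, 55.7% ± 2.56 in DKO AML and 46.9% ± 1.96 in treated DKO ERY. Within the granulocyte-monocyte-like class, a low-depth cluster (median UMIs at 0.390 of the library median) held 9.38% and 14.6% of kept cells in treated DKO ERY 1 and 2. It held 15.5% and 7.94% in DKO AML 1 and 2 and 2.03% to 4.71% in the other libraries. HSC/MPP-like cells were 24.1% ± 14.1 in the reference libraries, 22.1% ± 3.26 in DKO ERY, 14.7% ± 2.09 in DKO AML and 17.0% ± 3.03 in treated DKO ERY.

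**Figure D1:**
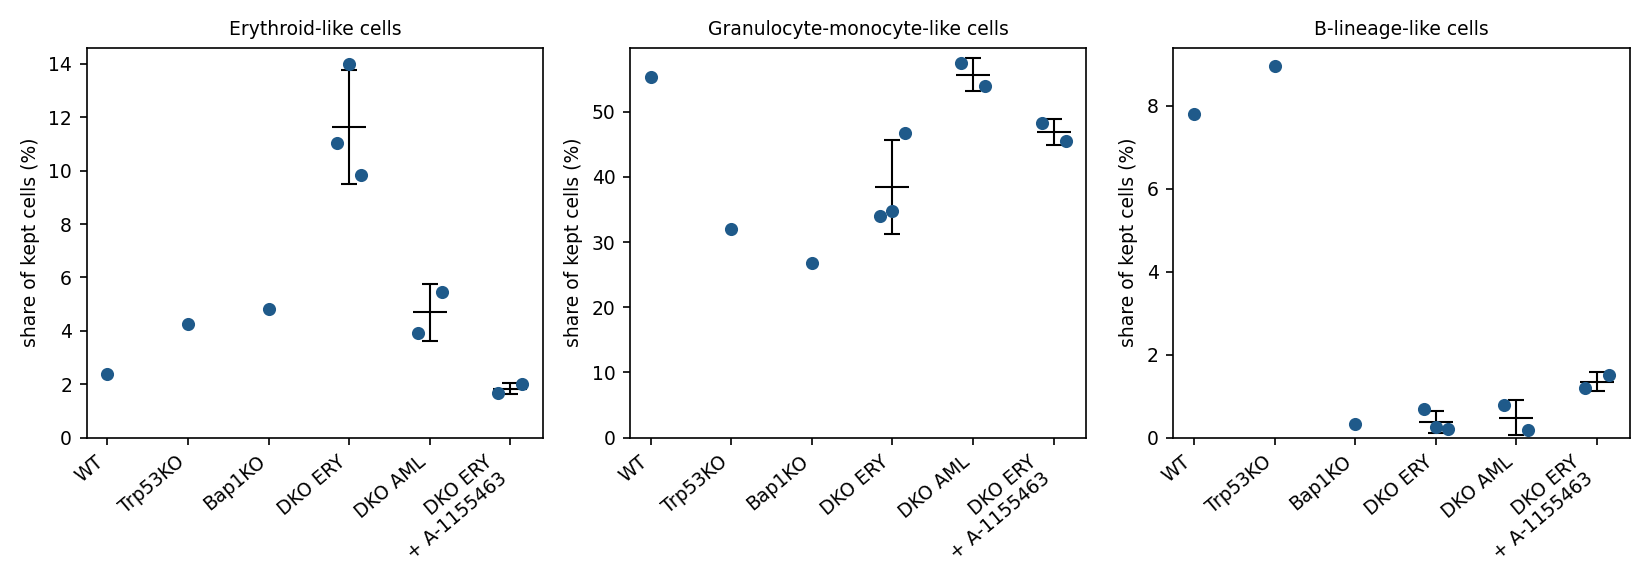
Share of kept cells (%, vertical axis) of erythroid-like, granulocyte-monocyte-like and B-lineage-like cells by group; each point is a mouse, and bars give the mean and SD of groups with at least 2 mice. Erythroid-like cells averaged 11.6% in DKO ERY, 4.69% in DKO AML and 1.84% in treated DKO ERY.

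The first comparison asked what distinguishes DKO ERY from progenitors that keep at least 1 of the genes. Early erythroid transcripts were higher in the 3 DKO ERY libraries than in the 3 reference libraries, and erythroid-like cells were 3.05 times as frequent. Klf1, a transcription factor of erythroid genes, rose by a log2 fold change of 2.36 ± 0.32 (SE; 28.3 against 5.52 CPM; adjusted p = 0.0338), and Rhag, a red cell membrane protein of the Rh complex, rose by 3.32 ± 0.51 (adjusted p = 0.0411). Gfi1b, a repressor needed for erythroid and megakaryocytic development, rose by 1.75, and Aqp1, the red cell water channel, rose by 1.61. Among late erythroid genes, Tspo2 rose by 3.16, Kel, a blood group antigen, by 2.08, and Snca by 1.63. The haem enzyme Cpox rose by 1.21 and the iron reductase Steap3 by 0.94.

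Over all genes, 122 of 18150 passed the threshold (49 higher and 73 lower in DKO ERY; 3716 at an unadjusted p under 0.05). Ocel1 (ENSMUSG00000002396, chromosome 8, 71371298 to 71379361) was the sole higher gene that met the naming rule, at 52.6 ± 8.71 CPM (SD, n = 3) against 20.9 ± 4.26 (n = 3), a log2 fold change of 1.33 ± 0.18 (adjusted p = 0.0338). The naming rule gave 10 lower genes. Pag1, an adaptor that restrains Src kinases (ENSMUSG00000027508, chromosome 3, 9687479 to 9833679), fell from 108.8 ± 12.3 to 48.2 ± 4.85 CPM (log2 fold change −1.17 ± 0.13, adjusted p = 0.0265). Plaur, the urokinase receptor, changed by −1.40, Vcl, the adhesion protein vinculin, by −1.21, Calcrl, a peptide hormone receptor, by −0.99, and the tetraspanin Tspan13 by −0.87. The kinase Stk17b changed by −1.23, the ubiquitin-conjugating enzyme Ube2h by −1.07, the transcription factor Mef2a by −0.89, Tbc1d1 by −0.77 and Ubl3 by −0.76.

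Of 27 gene lists, 8 passed camera. All 22 early erythroid genes had positive fold changes (median log2 1.68; 4 rose over all genes and 19 adjusted over the list alone; adjusted p = 5.1e-26, and adjusted p = 0.320 with an estimated correlation). Of 20 late erythroid genes, 3 rose (5 adjusted over the list alone; median 0.68; adjusted p = 0.000584, 0.641 with an estimated correlation), and of 21 genes of haem synthesis and iron, 2 rose (9 rose and 1 fell adjusted over the list alone; median 0.44; adjusted p = 1.2e-06, 0.641 with an estimated correlation). All 20 genes of MYC and ribosome biogenesis had positive values, but none passed over all genes (3 adjusted over the list alone; median 0.32; adjusted p = 2.0e-05, 0.641 with an estimated correlation). DNA repair genes had a median of 0.23 (2 of 18 adjusted over the list alone; adjusted p = 0.0284, 0.913 with an estimated correlation). Among 27 p53 targets, 1 fell (Perp, a desmosome protein, −2.48, at 0.452 against 2.51 CPM; adjusted over the list alone, 9 fell and 1 rose), with a median of −0.49 (adjusted p = 0.000428, 0.5999 with an estimated correlation). B lineage genes had a median of −3.63 (10 of 12 fell adjusted over the list alone; adjusted p = 7.9e-08, 0.641 with an estimated correlation), and immediate-early stress genes, induced within minutes of a stimulus, had −0.61 (0 of 17 adjusted over the list alone; adjusted p = 0.0317, 0.913 with an estimated correlation). By list score per library (chosen after the data were seen), DKO ERY overlapped the reference libraries for B lineage, immediate-early and DNA repair genes and lay apart from them for the other 5. The immediate-early score was −1.09, 0.43 and 0.96 in DKO ERY, 1.36 in Trp53KO and 1.37 in Bap1KO but −0.44 in WT, so DKO ERY 2 and 3 lay above WT. The integrated stress response list was not called (median 0.00), although its member Stc2 rose by 1.87 at about 1.19 CPM.

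The other lists were not called in this comparison. Their medians were −0.20 for anti-apoptotic and −0.02 for pro-apoptotic BCL2 family members, −0.02 for BAP1 partners and polycomb, 0.01 for stem cell genes, −0.21 for HoxA and Meis genes, −1.29 for neutrophil granules, −0.36 for monocytes, 0.28 for megakaryocytes, −0.19 for basophils and mast cells, 0.08 for T and NK cells, −1.85 for macrophages, −0.07 for stroma and endothelium, 0.03 for S phase, −0.16 for G2/M phase, −0.27 for interferon response, −0.20 for MHC class II, 0.14 for cholesterol synthesis and 0.14 for glycolysis and hypoxia. For basophils and mast cells (mean 0.05) and for glycolysis and hypoxia (mean −0.02), the mean had the other sign than the median. B lineage markers, of another cell type, were thus called beside the erythroid genes.

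By cell share, the erythroid-like difference gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give, with no overlap between the sets, while the granulocyte-monocyte-like shares (38.5% against 38.1% ± 15.2) gave p = 1. The count of 122 rested on single libraries: it was 2050 without WT, 16 without Trp53KO, and 2, 1 and 4 without DKO ERY 1, 2 and 3, while it was 1 with sex as a term, 0 with only these 6 libraries in the fit and 68 (34 higher and 34 lower) without TMM.

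**Figure D2:**
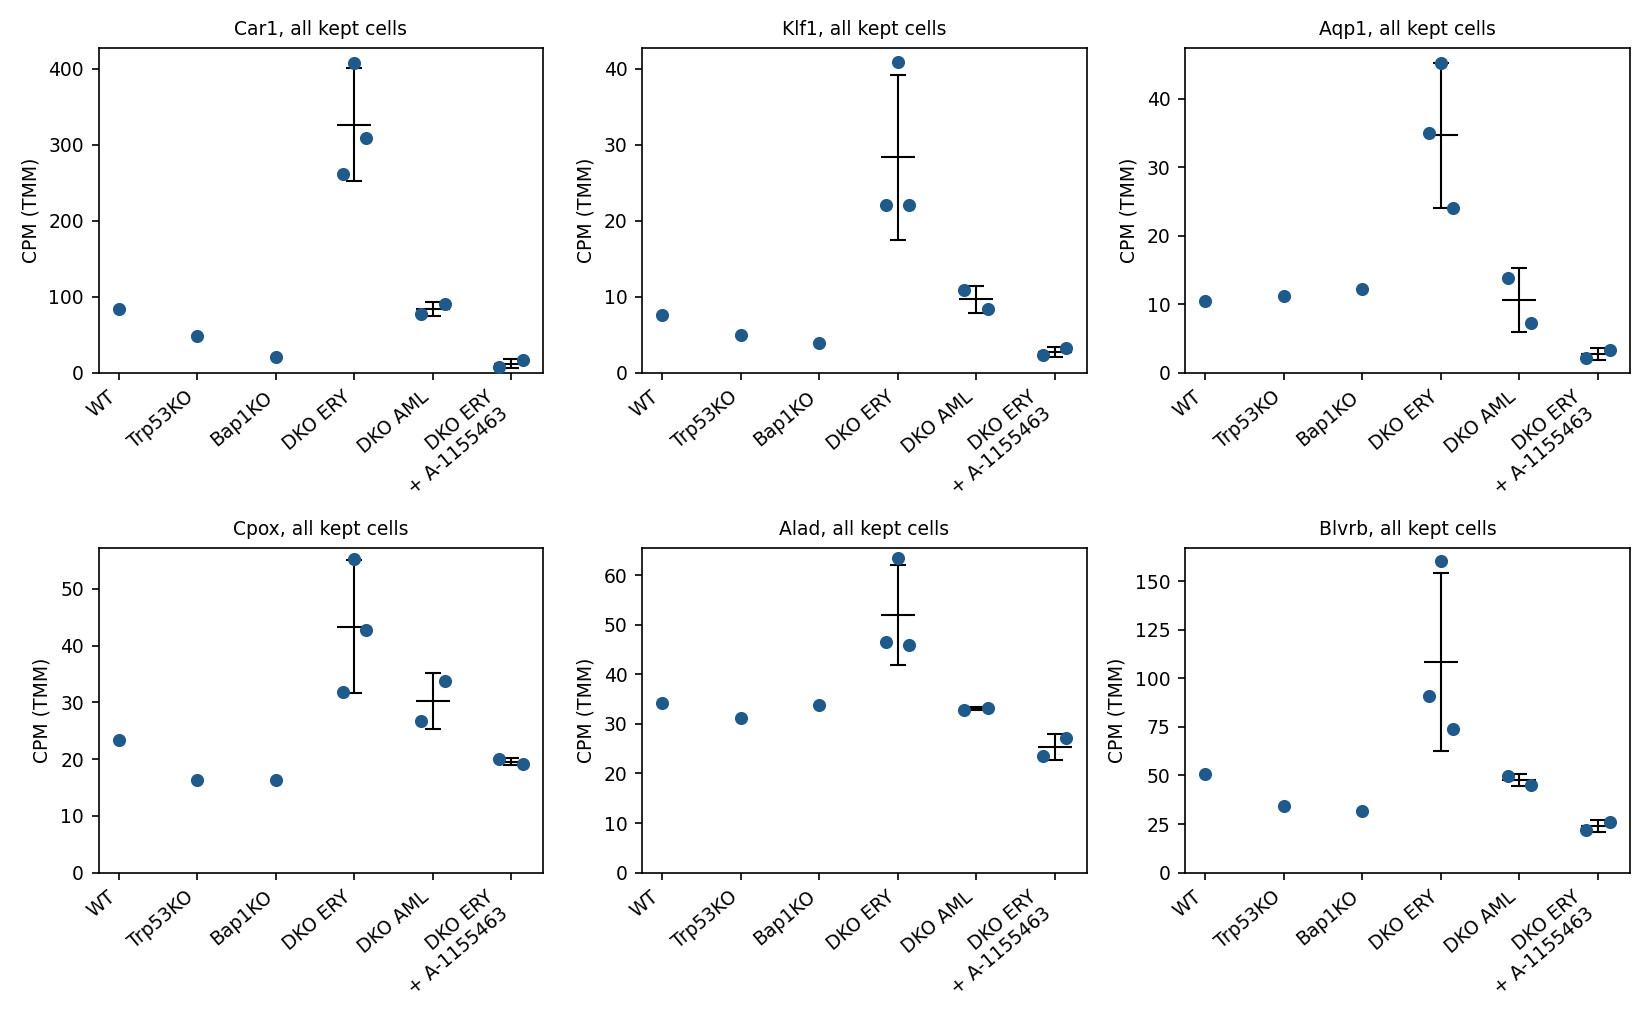
CPM over all kept cells (vertical axis, from 0) of Car1, Klf1, Aqp1, Cpox, Alad and Blvrb by group; each point is a mouse, and bars give the mean and SD of groups with at least 2 mice. Klf1 was at 22.0 to 40.8 CPM in DKO ERY and at 10.9 CPM or less in the other libraries.

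The next comparison asked the same of DKO AML. Here the list of MYC and ribosome biogenesis had higher values, and the lists of HoxA and Meis genes and of MHC class II had lower ones, in the 2 DKO AML libraries than in the 3 reference libraries, by camera with the preset correlation alone. Myc, the transcription factor that drives growth and ribosome production, rose by a log2 fold change of 0.89 ± 0.17 (adjusted p = 0.0313; 111.8 against 60.1 CPM), and Srm, the spermidine synthase (ENSMUSG00000006442, chromosome 4, 148591503 to 148594993), rose by 1.34 ± 0.31 (adjusted p = 0.0463; 284.8 ± 158.1 against 112.4 ± 20.8 CPM). Nfkbia, an inhibitor of NF-kappaB (ENSMUSG00000021025, chromosome 12, 55489410 to 55492647), changed by −2.75 ± 0.64 (adjusted p = 0.0491; 66.4 ± 6.73 against 446.5 ± 267.3 CPM), and Maml2, a Notch coactivator (ENSMUSG00000031925, chromosome 9, 13297957 to 13709388), changed by −1.99 ± 0.31 (adjusted p = 0.0231; 16.6 ± 0.987 against 66.0 ± 19.8 CPM). Mpo, the myeloperoxidase of neutrophil granules, rose by 1.03, to 5194 CPM from 2546. The neutrophil granule list as a whole was not called (median −0.23). Its score was 0.91 and 0.17 in DKO AML 1 and 2, 1.68 in WT, 0.13 in Trp53KO and −1.54 in Bap1KO.

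In all, 811 of 18150 genes passed the threshold (390 higher and 421 lower; 5491 at an unadjusted p under 0.05). Of the named higher genes, the tRNA synthetase subunit Farsb rose by 1.16, the synthetase complex member Eef1e1 by 1.08, the mitochondrial ribosomal protein Mrps18b by 1.06 and the complex I assembly factor Ndufaf4 by 1.12. Nkg7, a granule membrane protein, rose by 1.59, Comtd1 by 1.36, the collagen-modifying enzyme Plod3 by 1.31, Scamp3 by 1.09 and the protease inhibitor Spint2 by 1.06. Among the named lower genes besides Nfkbia and Maml2 were Nfkbiz, another member of the inhibitor family (−1.81), Cobll1 (−2.91), Zswim6 (−2.07), Fam102b (−1.92), Stk17b (−1.82), the membrane skeleton gene Epb41l2 (−1.72) and Tspan13 (−1.58). Hist1h2ap (−2.31) belongs to a family of near-identical histone genes, so its value is uncertain.

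Of 27 lists, 12 passed camera, and with an estimated correlation none did (adjusted p = 0.803 for each of the 12). Of 20 genes of MYC and ribosome biogenesis, 5 rose (Myc, Srm, Polr1b, Bop1 and Rrp9; 11 adjusted over the list alone; median 0.44; adjusted p = 1.4e-05). In the integrated stress response, 2 of 18 rose, Stc2 by 3.40 and the transcription factor Atf5 by 1.41 (5 rose and 1 fell adjusted over the list alone; median 0.44; adjusted p = 0.00330). DNA repair (median 0.42, adjusted p = 0.00343, 5 adjusted over the list alone), G2/M phase (0.41, adjusted p = 0.00459, 0 adjusted over the list alone), S phase (0.19, adjusted p = 0.0160, 0), haem synthesis and iron (0.31, adjusted p = 0.0299, 0) and early erythroid genes (0.63, adjusted p = 0.00459, 2) also had positive medians. Within the last list, Rhag rose by 2.68. The G2/M score was 0.160 and 0.591 in DKO AML 1 and 2 and 0.567 in WT, but −0.425 in Trp53KO and −0.292 in Bap1KO, so DKO AML did not clearly exceed WT. S phase (−0.0113 and 0.380, with 0.0884 in WT), haem synthesis and iron, MHC class II and B lineage scores also overlapped between the sets.

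Lower were the HoxA and Meis list, genes of self-renewing progenitors, where Hoxa5 (−1.69), Hoxa7 (−1.25) and Hoxa9 (−0.92) fell (3 of 12; 4 adjusted over the list alone; median −1.01; adjusted p = 0.000267), and MHC class II, where H2-Ob (−1.24), H2-Oa (−1.11) and H2-DMa (−1.04) fell (3 of 9; 4 adjusted over the list alone; median −0.90; adjusted p = 0.000837). The immediate-early list had a median of −1.99 (0 of 17 over all genes, 14 adjusted over the list alone; adjusted p = 5.8e-05), and the list's score among the reference libraries was 1.36 in Trp53KO and 1.37 in Bap1KO but −0.44 in WT. Nfkbia, likewise, was at 141.6 CPM in WT, 557.5 in Trp53KO and 640.5 in Bap1KO. The HoxA and Meis list also stood apart within the reference. In Trp53KO 6 of 6 members were higher than in WT (percentile 99.31 of random lists) and in Bap1KO 5 of 6 (percentile 99.59), with Hoxa9 at 1.57 and 1.59 times WT and Meis1 at 2.16 and 2.41 times. B lineage genes had −3.27 (0 adjusted over the list alone; adjusted p = 0.00226). Of 27 p53 targets, Mdm2, the p53-induced ubiquitin ligase that degrades p53, fell by 0.94 on the log2 scale (6 fell and 1 rose adjusted over the list alone; median −0.46; adjusted p = 0.00459). Outside the called lists, the pro-apoptotic gene Bcl2l11 (−1.93), the polycomb genes Rnf2 (−0.74) and Jarid2 (−0.52), the megakaryocyte genes Plek (−1.54) and Clec1b (−1.72) and the glucose transporter Slc2a3 (−1.44) fell. The median, mean and test differed in sign for the uncalled lists of neutrophil granules (median −0.23, mean 0.02), BAP1 partners and polycomb (0.05 and −0.04) and pro-apoptotic BCL2 family members (0.03 and −0.38).

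The erythroid-like share (4.69% against 3.82% ± 1.28) gave an exact two-sided permutation p of 0.6, and the granulocyte-monocyte-like share (55.7% against 38.1%) gave 0.3, where 0.1 is the smallest possible. This difference of 17.6 points was 10.1 with the clustering resolution doubled, 26.3 without WT, 11.97 without Bap1KO, 26.8 with each cell named by its own markers and 27.6 without correction for library (chosen after the data were seen). The low-depth cluster of that class held 15.5% and 7.94% of kept cells in DKO AML 1 and 2, against 2.03% to 4.30% in the reference libraries. The share without that cluster was not compared. The count of 811 was 4888 without WT, 12 without Trp53KO, 250 without Bap1KO, 2173 without DKO AML 1 and 1 without DKO AML 2, and it was 0 with only these 5 libraries in the fit, 29 with the immediate-early score as a term (chosen after the data were seen), and 1063 with 66.9% higher in place of 48.1% without TMM.

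**Figure D3:**
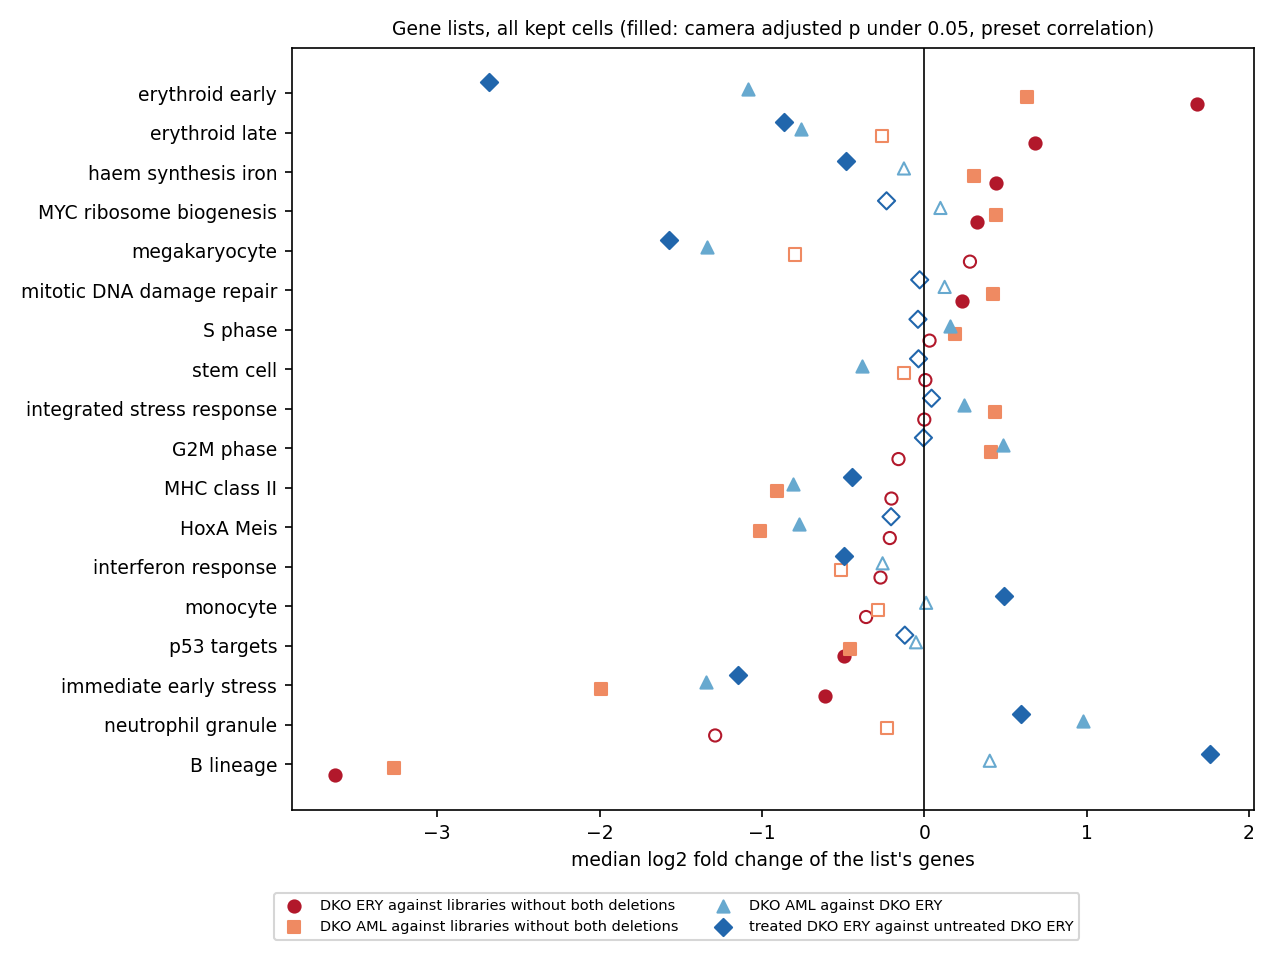
Median log2 fold change (horizontal axis) of each gene list with a call, over all kept cells, in 4 comparisons; filled symbols mark a camera adjusted p under 0.05 with the preset correlation. Early erythroid genes had medians of 1.68 in DKO ERY against the reference libraries and −2.68 in treated against untreated DKO ERY.

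DKO AML and DKO ERY share a genotype and differ in the label of the disease. Erythroid-like cells were 2.48 times as frequent in DKO ERY, and early erythroid genes had the lower values in DKO AML, while neutrophil granule genes, such as those of primary granule proteases, had the higher ones. All 21 neutrophil granule genes had positive fold changes in DKO AML (median 0.98; 0 adjusted over the list alone; adjusted p = 3.9e-07, 0.670 with an estimated correlation), as did all 22 G2/M genes (0.49; 0 adjusted over the list alone; adjusted p = 3.9e-07, 0.735 with an estimated correlation). Of 22 early erythroid genes, 21 had negative values (median −1.09; 8 fell adjusted over the list alone; adjusted p = 9.6e-12, 0.442 with an estimated correlation).

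At the level of single genes, 1 of 18150 passed (2321 at an unadjusted p under 0.05; DESeq2 416). It was Gm45356 (ENSMUSG00000110162, chromosome 8, 57699774 to 57727344; adjusted p = 0.0304), an unnamed gene model outside the naming rule and picked after its values were seen, with 80 and 133 UMIs in the DKO AML libraries and 0 in all 3 DKO ERY libraries. The treated DKO ERY libraries held 38 and 40 UMIs of it, and WT, Trp53KO and Bap1KO held 6, 7 and 16, so it does not follow the AML and ERY labels over all mice. Lower lists in DKO AML were megakaryocyte genes (median −1.34; 2 fell adjusted over the list alone; adjusted p = 3.9e-07, 0.442 with an estimated correlation), HoxA and Meis genes (−0.77, 1 fell; adjusted p = 5.8e-06, 0.442), MHC class II (−0.81, 3 fell; adjusted p = 3.0e-06, 0.442), late erythroid genes (−0.76, 0; adjusted p = 0.000115, 0.510), immediate-early genes (−1.34, 0; adjusted p = 0.000165, 0.828) and stem cell genes (−0.39, 0; adjusted p = 0.0351, 0.837). The immediate-early score was −0.81 and −0.65 in DKO AML, above DKO ERY 1 (−1.09) and below DKO ERY 2 and 3 (0.43 and 0.96), so that call rests on the latter. S phase (0.16, 0; adjusted p = 0.0156, 0.837 with an estimated correlation; scores overlapped) and the integrated stress response (0.24, 5 rose; adjusted p = 5.3e-05, 0.442) were the other higher lists. Uncalled lists whose median and mean differed in sign were anti-apoptotic (−0.04 and 0.05) and pro-apoptotic BCL2 family members (0.07 and −0.08) and macrophages (0.02 and −0.01).

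The exact two-sided permutation p was 0.1 for the erythroid-like share, the smallest possible with 2 against 3 libraries, and 0.2 for the granulocyte-monocyte-like share (55.7% against 38.5%), a difference of 17.2 points that was 10.4 with the clustering resolution doubled. The low-depth cluster was again larger in DKO AML (15.5% and 7.94%) than in DKO ERY (3.04% to 4.71%). The count of 1 gene rose to 104 without DKO AML 1 and was 0 without any other library of these sets in turn, and it was 64 with only these 5 libraries in the fit, 3 without TMM (2 higher) and 11 with no filter on low counts.

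The last tested comparison asked what followed A-1155463 in DKO ERY. Erythroid transcripts were far lower in the 2 treated than in the 3 untreated libraries, and erythroid-like cells were 6.32 times as frequent without treatment. Car1, an erythroid carbonic anhydrase (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368), was at 12.1 ± 5.92 CPM (SD, n = 2) against 326.2 ± 74.5 (n = 3), a log2 fold change of −4.76 ± 0.64 (adjusted p = 0.0238). Aqp1 changed by −3.63 ± 0.38 (adjusted p = 0.00834), Klf1 by −3.36 ± 0.40 (adjusted p = 0.0134), Epor, the erythropoietin receptor, by −3.12 ± 0.48 (adjusted p = 0.0246) and Snca by −2.93. The haem enzymes Urod (−1.06) and Alad (−1.04), the iron reductase Steap3 (−1.01), and Blvrb, biliverdin reductase B (−2.18), fell too.

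Of 18150 genes, 138 passed (81 higher in treated libraries and 57 lower; 2508 at an unadjusted p under 0.05). The mitochondrial carrier Slc25a21 (ENSMUSG00000035472, chromosome 12, 56712634 to 57197472) changed by −4.04, and Nfia, a transcription factor of erythroid fate, by −1.42. Gstp1, a glutathione transferase (ENSMUSG00000060803, chromosome 19, 4035407 to 4037985), fell from 57.1 ± 8.49 to 15.4 ± 0.0665 CPM (−1.89 ± 0.16, adjusted p = 0.00683). Its near-identical neighbours in the family leave its counts uncertain, as processed copies do for the ribosomal protein gene Rpl10 (−0.94). Within granulocyte-monocyte-like cells, Gstp1 was also low in untreated DKO AML, at 20.6 and 20.7 CPM, against 15.7 and 15.2 CPM in treated DKO ERY. A low Gstp1 level was thus not particular to treatment. Mns1 changed by −1.87, Ocel1 by −1.41 and Borcs8 by −1.14. Higher in the treated libraries were Snhg9, a small nucleolar RNA host gene (2.10; 103.7 ± 17.1 against 24.2 ± 5.52 CPM, adjusted p = 0.0467), Cxcr4, the receptor that retains progenitors in marrow (1.59; 52.4 ± 0.304 against 17.4 ± 4.15 CPM, adjusted p = 0.0422), and Ccdc162 (1.54). Snhg9 and Ccdc162 were also among the top 10 genes of an unnamed cluster, with the antibody genes Igha, Igkc and Jchain, that held 3.55% and 2.44% of the treated cells, 3.22% of DKO AML 1 and at most 0.693% of any other library. Within granulocyte-monocyte-like cells they were at 71.4 and 52.4 CPM in untreated DKO AML 1, the highest of the libraries without treatment. Of kept cells, 67.9% and 73.0% met the stricter cell filters in the treated libraries, 72.5% in DKO AML 1 and 92.7% to 96.1% in the others.

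Of 27 lists, 10 passed camera. Of 22 early erythroid genes, 8 fell (20 adjusted over the list alone; median −2.68; adjusted p = 8.6e-45, 0.0515 with an estimated correlation), of 20 late ones 1 fell (9 adjusted over the list alone; −0.86; adjusted p = 2.5e-10, 0.250 with an estimated correlation), and of 21 genes of haem synthesis and iron 3 fell (9 adjusted over the list alone; −0.48; adjusted p = 1.3e-08, 0.397 with an estimated correlation). Megakaryocyte genes had a median of −1.58 (0 over all genes, 9 adjusted over the list alone; adjusted p = 3.1e-09, 0.260 with an estimated correlation). The following had 0 members past the threshold, over all genes or adjusted over the list alone. Neutrophil granule (0.59, adjusted p = 0.00181), monocyte (0.49, adjusted p = 0.0110) and B lineage genes (1.76, adjusted p = 0.000140) had positive medians, and immediate-early (−1.15, adjusted p = 0.00763), interferon response (−0.50, adjusted p = 0.0313) and MHC class II genes (−0.45, adjusted p = 0.0313) had negative ones, with adjusted p = 0.945 for interferon response and 0.909 for the other 5 with an estimated correlation. The immediate-early score of both treated libraries (−0.45 and −0.67) lay above that of DKO ERY 1 (−1.09), and interferon response scores overlapped too. The BCL2 family lists were not called (medians −0.52 for anti-apoptotic and −0.15 for pro-apoptotic members). Without TMM, the median of all genes shifted from −0.03 to 0.16, and the uncalled lists of p53 targets, pro-apoptotic BCL2 family, stem cell, S phase, G2/M phase, T and NK, glycolysis and DNA repair genes turned from negative to positive medians.

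The erythroid-like share gave an exact two-sided permutation p of 0.1, the smallest possible with 2 against 3 libraries, and the granulocyte-monocyte-like share (46.9% against 38.5%) gave 0.3. The latter difference of 8.42 points was 0.466 with the clustering resolution doubled and 2.46 with stricter cell filters. The low-depth cluster of that class held 9.38% and 14.6% of the treated cells and 3.04% to 4.71% of the untreated ones. With the resolution doubled, a cluster of lower depth still (0.178 of the library median) stayed unnamed and held 7.92% and 13.1% of the treated cells. The difference thus rests on how cells of low depth are named. The count of 138 was 0 without either treated library, 19, 13 and 35 without DKO ERY 1, 2 and 3, 19 with sex as a term, 61 with the immediate-early score as a term and 0 without DKO ERY 2 and 3 (the last pair chosen after the data were seen), 884 with only these 5 libraries in the fit, and 189 with 75.1% higher in place of 58.7% without TMM.

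Within erythroid-like cells alone, the question was whether cells of 1 class differed, apart from how many there were. The class was itself a mix. With the clustering resolution doubled, the cluster with the most cells of the 3 in this class held 57.1% of these cells in WT, 78.1% in Trp53KO, 66.7% in Bap1KO, 53.8% to 58.4% in DKO ERY, and 41.1% and 58.2% in DKO AML 1 and 2. The genes below may therefore reflect that mix. DKO AML cells had lower Tcf4, a transcription factor of plasmacytoid dendritic and lymphoid cells (log2 fold change −2.31 ± 0.32, adjusted p = 0.0346; 20.5 ± 6.78 against 100.6 ± 16.2 CPM), S100a10 (−1.75), the polymerase subunit Znrd1 (−1.72), the phospholipase Plcb4 (−1.66) and Dock7 (−1.502) than those of the reference libraries. In that comparison 18 of 11678 genes passed (4 higher and 14 lower; 2677 at an unadjusted p under 0.05). On simulated counts 6.4% of calls were false, but the simulated libraries shared their means within a set, so this share need not hold for the 18. DKO ERY gave 0 genes with edgeR against the reference libraries (2031 at an unadjusted p under 0.05; DESeq2 156), and DKO AML against DKO ERY gave 0 (832 at an unadjusted p under 0.05; DESeq2 53). Erythroid-like cells numbered 93 in WT, 141 in Trp53KO, 180 in Bap1KO and 121 to 675 in the untreated DKO libraries, and without WT the counts were 3024 for DKO AML and 3026 for DKO ERY against the reference libraries. The count of 18 was 0 without Trp53KO or DKO AML 2, 2 without Bap1KO and 10 without DKO AML 1, and DKO AML against DKO ERY gave 12 genes without DKO AML 1 and 4 without DKO AML 2.

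Within granulocyte-monocyte-like cells, DKO AML had lower Tnfaip3 and Nfkbia and higher Gfi1, a repressor that promotes the granulocyte fate. Tnfaip3, a brake on NF-kappaB, changed by −3.81 ± 0.83 (adjusted p = 0.0436; 5.40 ± 3.32 against 74.6 ± 33.9 CPM), and Nfkbia by −3.01 ± 0.64 (adjusted p = 0.0397), with 141.2 to 618.4 CPM among the reference libraries. The phosphodiesterase Pde4b (−2.88), Crebrf (−2.84) and the pro-apoptotic Bcl2l11 (−2.65) fell as well. Among the reference libraries, Tnfaip3 ranged over 37.0 to 102.6 CPM, Pde4b over 74.0 to 270.3, Crebrf over 22.9 to 105.2 and Bcl2l11 over 23.6 to 72.0. Gfi1 (1.52), Plpp5 (1.497), Spint2 (1.40), Sigmar1 (1.25) and Srm (1.25) rose. The immediate-early score was used as a term over all kept cells only. Whether that signal in Trp53KO and Bap1KO carries these changes was not tested within the class. Of 15674 genes, 753 passed (278 higher and 475 lower; 4588 at an unadjusted p under 0.05). The class was a mix here as well. A late-neutrophil cluster topped by Ngp, Camp and Ltf made up 29.8% of it in WT, 13.8% in Trp53KO, 3.70% in Bap1KO, and 17.9% and 5.54% in DKO AML 1 and 2. Without that cluster (chosen after the data were seen), 1048 genes passed (377 higher and 671 lower), and no named gene was lost. That fit kept a more mature neutrophil cluster, topped by Retnlg, Mmp8 and Mmp9. It held 5.40% of kept cells in WT and 0.383% to 2.37% in the other libraries, so the mix was only partly removed. The 20 genes named for DKO AML over all cells had the same sign within these cells, and 15 of them passed there too. These cells are a large part of the sums that picked those genes, so that overlap is partly built in. The count was 3883 without WT, 27 without Trp53KO, 272 without Bap1KO, 2756 without DKO AML 1 and 5 without DKO AML 2, while it was 0 with only these 5 libraries in the fit, 406 against WT alone and 569 with 57.5% higher in place of 36.9% without TMM.

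The same class was also compared for the other sets, a choice made after the data were seen. That late-neutrophil cluster held 2.85%, 4.41% and 5% of the class in DKO ERY 1, 2 and 3 and 13.9% and 5.36% in treated DKO ERY 1 and 2. These comparisons were not repeated without it, so the genes may reflect that mix. DKO ERY differed from the reference libraries in 46 genes (9 higher and 37 lower), with Ocel1 higher (1.41) and Pag1 (−1.65), Vcl (−1.64), Stk17b (−1.46), Plaur (−1.43) and Xpr1 (−1.36) lower, and all 11 genes named over all cells had the same sign (7 passed). DKO AML differed from DKO ERY in 7 genes, of which Serpinf1, the secreted factor PEDF, met the naming rule (−1.94, adjusted p = 0.0403; 13.1 ± 3.34 against 50.4 ± 10.0 CPM). Treated and untreated DKO ERY differed in 12 genes (9 higher and 3 lower), with Gstp1 lower (−1.90, adjusted p = 0.0151), though it was nearly as low in untreated DKO AML (20.6 and 20.7 CPM). Of the 13 genes named over all cells for treatment, 11 had the same sign and 2, Gstp1 and Mns1, passed. Blvrb (0.01) and Nfia (0.09) were near 0. For DKO ERY and for treatment too, shared signs are partly built in, because these cells entered the sums that picked the genes.

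Single deletions were set against WT with 1 library each, so the ratios below describe these libraries and their intervals cover counting error only. In both Trp53KO and Bap1KO, immediate-early and megakaryocyte lists lay above WT, and the neutrophil granule list lay below it. Rgs1, a regulator of chemokine receptor signalling, was 18.2-fold higher in Trp53KO (95% interval 17.2 to 19.3) and 24.1-fold higher in Bap1KO, and the stress-induced transcription factor Atf3 was 10.2-fold and 12.4-fold higher. All 17 measured immediate-early genes were higher in Trp53KO (median log2 ratio 1.71, percentile 100 of random lists), as were all 15 in Bap1KO (1.76, percentile 100). The median of neutrophil granule genes was −1.70 in Trp53KO and −3.02 in Bap1KO (percentile 0 in both), and Camp, a secondary granule peptide, had a ratio of 0.0265 in Bap1KO. B lineage genes had a median of −3.69 in Bap1KO (percentile 0) and −0.41 in Trp53KO (percentile 1.22).

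Further genes higher in Trp53KO were Hes1, a Notch target (9.95-fold), Pf4, a platelet chemokine (8.51-fold), Ccl3 (7.46-fold), Ccl4 (6.72-fold), Ccl5 (6.66-fold), Mid1 (5.89-fold), Egr1 (5.60-fold) and Cxcl2 (5.47-fold). Lower there were Jchain (ratio 0.00146), the antibody joining chain of plasma cells, and, with ratios of 0.128 to 0.196, Rflnb, Dmkn, Fgr, AI506816, Lrg1, Chil1, Fcnb, Nrg1 and Cd177. In Bap1KO, Lhfpl4 (84.8-fold, interval 65.4 to 112.1), Eif3j2 (21.6-fold), Creb5 (18.8-fold), Nr4a1 (15.6-fold), Pf4 (10.7-fold), Ccl4 (10.3-fold), Skil (8.46-fold) and Ctla2b (8.07-fold) were higher. Eif3j2 is a near-copy of Eif3j1, so its counts are uncertain. Lower were Fcnb (0.0191), Chil1 (0.0230), the B-cell receptor surrogate genes Vpreb3 (0.0287) and Igll1 (0.0291), Lrg1 (0.0296), Abca13 (0.0307), Ngp (0.0322), S100a8 (0.0326) and Chil3 (0.0328).

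A test chosen after the data were seen took the spread from the replicated groups and assumed that the lone libraries vary like them. Of 19011 genes, 174 passed for Trp53KO against WT (86 higher and 88 lower), with 3152 at an unadjusted p under 0.05 and 1087 by DESeq2. For Bap1KO against WT, 1482 passed (603 higher and 879 lower), with 4586 unadjusted and 2287 by DESeq2. Of the 20 genes named by ratio in each, 4 passed for Trp53KO (Rflnb, Fgr, AI506816 and Nrg1, all lower). For Bap1KO 5 passed, with Ctla2b and Pf4 higher and Abca13, Fcnb and S100a8 lower. None of the 17 immediate-early genes passed with edgeR in either library (4 in Trp53KO and 7 in Bap1KO at an unadjusted p under 0.05, and 3 and 6 by DESeq2). Of 27 p53 targets, 0 passed for Trp53KO with edgeR (7 unadjusted, and 5 by DESeq2). In Bap1KO, Cdkn1a, Bbc3, Ddit4 and Tnfrsf10b were higher and Pltp was lower. The count of 174 was 5 without DKO ERY 2, and 529 and 530 without DKO AML 1 and 2. It was 6 and 32 without treated DKO ERY 1 and 2, and 300 without TMM (222 higher and 78 lower). The count of 1482 was 978 without DKO ERY 2 and 831 and 837 without treated DKO ERY 1 and 2.

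The p53 target list had a slightly negative median in the library labelled Trp53KO (−0.21, percentile 9.45), with 7 of 19 genes higher and the rest lower. It did not stand clearly apart from random lists, which does not show that the targets were unchanged. In Bap1KO the median was −0.05 (percentile 43.7; 10 of 20 higher). Cdkn1a, the p53-induced cell cycle inhibitor p21, was 2.61-fold higher in Trp53KO (interval 2.45 to 2.79) and 6.34-fold higher in Bap1KO (5.98 to 6.73), and Bbc3, the pro-apoptotic gene Puma, was 3.07-fold and 4.42-fold higher. Bax had a ratio of 0.679 in Trp53KO. Stem cell genes had medians of 0.53 in Trp53KO and 0.96 in Bap1KO (percentile 100 in both), megakaryocyte genes 1.58 and 1.87 (percentile 100), G2/M genes −0.95 and −0.79 (percentile 0; 22 of 22 lower in each), and early erythroid genes −0.10 (percentile 28.7) and 0.21 (percentile 93.9). HSC/MPP-like cells were 10.0% of kept cells in WT (9.09% to 10.99%), 24.1% in Trp53KO (22.7% to 25.6%) and 38.3% in Bap1KO (36.7% to 39.9%). Megakaryocyte-like cells were 1.25% (0.925% to 1.65%), 5.35% (4.61% to 6.17%) and 9.01% (8.11% to 9.98%). In Trp53KO 39.4% and in Bap1KO 31.4% of barcodes exceeded the mitochondrial limit, against 9.02% in WT.

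**Figure D4:**
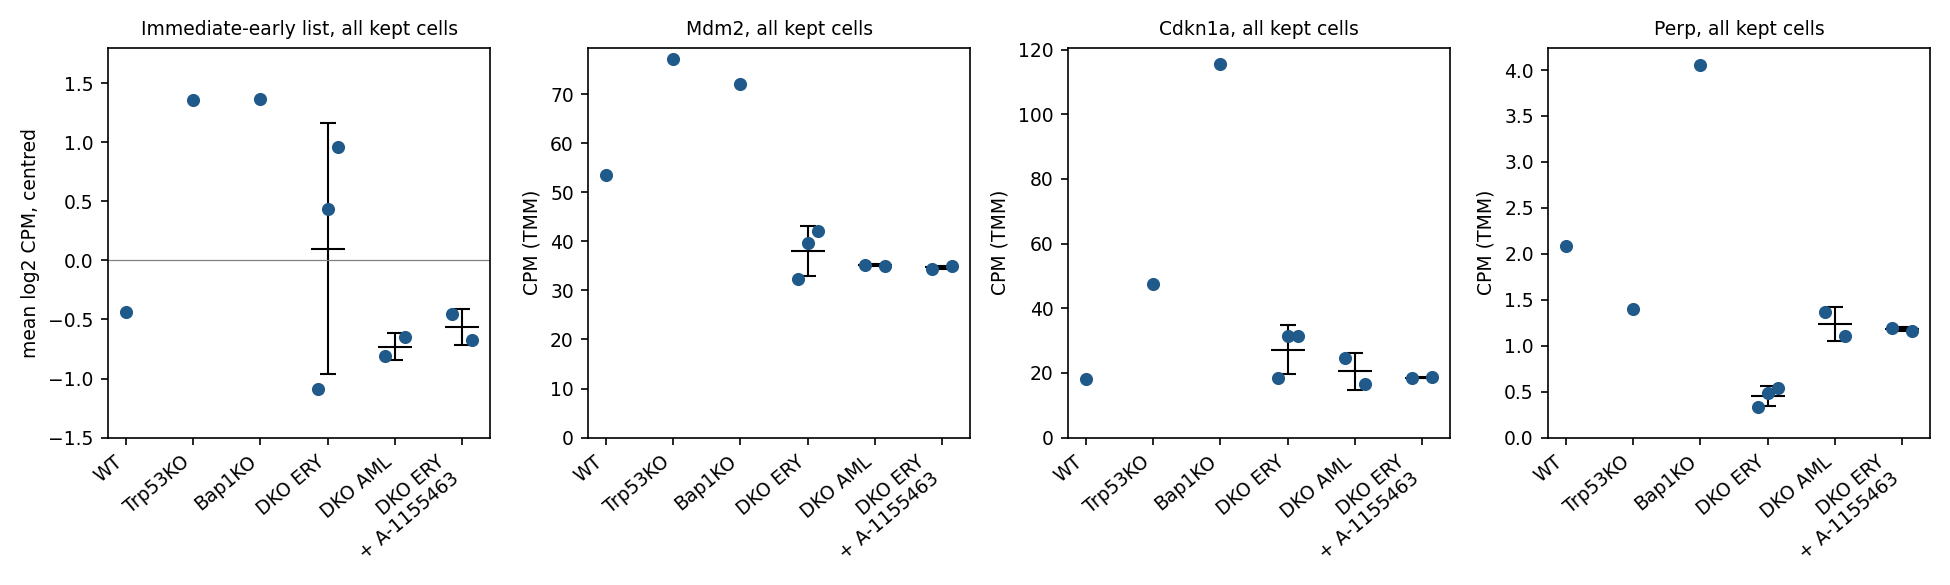
Mean log2 CPM of the immediate-early list, centred over libraries, and CPM of the p53 targets Mdm2, Cdkn1a and Perp by group, over all kept cells; each point is a mouse, and bars give the mean and SD of groups with at least 2 mice. The list's score was 1.36 in Trp53KO and 1.37 in Bap1KO, against −0.44 in WT.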

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

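All tests in this part were chosen after the result was seen, except the test of the cell filter and the test of a single class.

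The share of granulocyte-monocyte-like cells stood out because the Bap1 deletion went with opposite shifts by Trp53 label. It was 28.6 points lower in Bap1KO than in WT (difference −28.6), but 1.86, 2.66 and 14.7 points higher in DKO ERY 1, 2 and 3 than in Trp53KO, a contrast of 35.0 points that was not tested. The late-neutrophil cluster of this class held 16.5% of kept cells in WT and 0.990% in Bap1KO, so it carried much of that gap. The share of basophil/mast/eosinophil-like cells showed such opposite shifts in the other direction, at 2.30 points more in Bap1KO than in WT and at −1.28, −0.549 and −1.75 points in DKO ERY relative to Trp53KO, an untested contrast of −3.49 points. The same share was 0.746 points higher in the treated than in the untreated male DKO ERY mouse, and at −1.57 and −0.369 points in the treated female relative to the untreated females, an untested contrast of −1.72 points.

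Erythroid-like cells were scarcer in treated than in untreated DKO ERY (1.84% against 11.6% of kept cells). Loss of erythroid-like cells to the filter on cells stays open in part. The early erythroid list summed to 272.6 and 382.5 CPM over all deposited barcodes of the treated libraries. It summed to 1064, 1427 and 925 CPM in the untreated ones, a ratio of means of 0.288. These sums argue against a loss of erythroid-like cells that held many UMIs. They weight each barcode by its UMIs, however. They therefore cannot tell whether erythroid-like cells were lost among barcodes below the UMI or gene minimum. Dilution by low-quality barcodes or by mature cells among the kept cells is excluded as the whole explanation, but not as a part of it. In the treated libraries there were 0.113 and 0.104 erythroid-like cells per HSC/MPP-like cell. In the untreated ones there were 0.430, 0.654 and 0.510, a ratio of 0.205. The treatment stays open, because an exact permutation p of 0.1 is the smallest that 2 against 3 libraries allow. A difference between the mice in disease stage or time of sampling, on which the labels are silent, stays open with it.

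Immediate-early transcripts were high in the libraries labelled Trp53KO and Bap1KO, by 1.801 on the log2 scale over WT, although 0 of the 17 genes passed a test of either library against WT (edgeR, with 4 and 7 unadjusted and 3 and 6 by DESeq2). The high counts were not confined to cells of 1 class. Both libraries lay above WT, DKO ERY 1 and both DKO AML libraries in 4 of 4 class sums (erythroid-like, granulocyte-monocyte-like, HSC/MPP-like and megakaryocyte-like). DKO ERY 2 and 3, which scored 0.43 and 0.96, were not among the libraries compared. Transcripts carried over between droplets were not removed, so a release by cells of 1 class stays open. The genotype alone stays open, because each is 1 library, while the 3 DKO ERY libraries, which share a genotype, spanned 2.05, so other factors can move the list as far. Handling of the tissue may account for it and stays open, as the labels hold no record of it. With the list's score as a term, 29 genes in place of 811 passed for DKO AML against the reference libraries, and the score and the sets partly coincide, so that count cannot tell the handling from the groups.

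The p53 targets had only a slightly negative median in the library labelled Trp53KO (median log2 ratio −0.21 against WT). The list did not stand clearly apart from random lists, so whether the targets were lower is undecided. A candidate explanation for so small a difference is that the immediate-early signature raises some targets. All 5 of the 5 targets at least 1.5 times as high as in WT were also higher in DKO ERY 2 and 3 than in DKO ERY 1. On the immediate-early list, DKO ERY 2 and 3 scored 0.43 and 0.96, and DKO ERY 1 scored −1.09. That test decides nothing, because 8 of the 15 other targets met the same condition. A wrong label or a partial deletion stays open as well, with 9 of 20 measured targets lower in Trp53KO than in both WT and Bap1KO, and the 3' counts of Trp53 check neither.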

How the results depend on the processing

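The alternatives with an immediate-early score, without Trp53KO and Bap1KO, without DKO ERY 2 and 3, without the late-neutrophil cluster, without correction for library, and the tests of Trp53KO and Bap1KO against WT were added after the result was seen. No paired analysis was possible because the labels carry no replicate numbers that pair mice. Where leaving out a library leaves 1 in an arm, the lone library is assumed to vary like the others.

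The erythroid-like share kept its sign in all 4 comparisons under every alternative run. The difference ranged from 6.63 to 9.07 points for DKO ERY against the reference libraries, 0.118 to 1.76 for DKO AML against them (0.149 without WT, 0.118 without DKO AML 2), −7.83 to −5.76 for DKO AML against DKO ERY and −11.5 to −8.61 for treated against untreated DKO ERY. The granulocyte-monocyte-like share of DKO ERY against the reference libraries (0.414 points) turned to −0.324 with the clustering resolution doubled, −0.403 with stricter cell filters and −5.24 to 9.06 leaving out each library in turn (−5.24 without Bap1KO, −2.58 without Trp53KO, −3.74 without DKO ERY 3, 9.06 without WT). It was 6.23 with each cell named by its own markers and 11.6 without correction for library. In the other 3 comparisons it kept its sign under the alternatives run but not its size. It ranged over 10.1 to 27.6 points (17.6 as reported) for DKO AML against the reference libraries, 10.4 to 21.4 (17.2) for DKO AML against DKO ERY and 0.466 to 12.6 (8.42) for treatment.

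Counts of genes past the threshold moved far more, and the cause was not tested. Over all kept cells, in the order DKO ERY and DKO AML against the reference libraries, DKO AML against DKO ERY, and treated against untreated DKO ERY, the counts of 122, 811, 1 and 138 became 1366, 2966, 416 and 748 with DESeq2, 0, 0, 64 and 884 with only the compared sets in the fit, and 1, 194, 0 and 19 with sex as a term. WT alone as the reference gave 1096 and 532 for the first 2. Leaving out each library in turn gave 1 to 2050, 1 to 4888, 0 to 104 and 0 to 35. Without TMM, DKO ERY gave 68 and DKO AML against DKO ERY gave 3. The latter also gave 11 with no filter on low counts, and 0 with stricter cell filters, with thinned libraries, with the immediate-early score and without DKO ERY 2 and 3 (edgeR; 1155 to 2289 genes at an unadjusted p under 0.05 in these fits, and DESeq2 416 with all libraries). With the immediate-early score as a term, DKO ERY against the reference libraries gave 162 (27.8% higher in place of 40.2%), DKO AML against them 29 and treatment 61. Without Trp53KO and Bap1KO, DKO ERY gave 1085, and without DKO ERY 2 and 3, treatment gave 0 (edgeR; 1141 unadjusted; DESeq2 748 with all libraries).

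Within erythroid-like cells, DKO ERY against the reference libraries (0 genes) gave 156 with DESeq2, 899 with no filter, 9 against WT alone and 0 to 3026 leaving out each library (3026 without WT). DKO AML against them (18) gave 844 with DESeq2, 8 without TMM (37.5% higher in place of 22.2%), 1495 with no filter, 1 with only the compared sets, 41 with stricter cell filters, 8 with doublets kept, 28 against WT alone, 10 with the resolution doubled and 0 to 3024 leaving out each library (3024 without WT). DKO AML against DKO ERY (0) gave 53 with DESeq2, 406 with no filter, 21 with only the compared sets and 0 to 12 leaving out each library. Without TMM, the median of all genes shifted to −0.16 for DKO ERY against the reference libraries and 0.19 for DKO AML against DKO ERY. Within granulocyte-monocyte-like cells, DKO AML (753) gave 2259 with DESeq2, 0 with only the compared sets, 406 against WT alone, 1048 without the late-neutrophil cluster and 5 to 3883 leaving out each library.

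Of the called gene lists, 41 by camera with the preset correlation, 0 passed with an estimated correlation and 1 with fry, the early erythroid list under treatment (fry adjusted p = 0.0147). By comparison, 8, 12, 11 and 10 became 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 1 with fry. None of the 41 changed the sign of its median without TMM or with DESeq2, whereas 10 of the 67 uncalled ones did. By list score per library, the compared sets lay apart for 29 of the 41 and overlapped for 12. The sign of every named gene was kept, with 1046 results on the same side of the threshold and 813 no longer past it. DESeq2 and leaving out WT lost 0 of them, while only the compared sets in the fit lost 96 of 115, WT alone as the reference 74 of 97 and sex as a term 67 of 82. The immediate-early score as a term lost 56 of 82. Leaving out Trp53KO lost 91 of 97 and leaving out Bap1KO 73 of 97. Leaving out DKO AML 1 lost 22 of 75 and leaving out DKO AML 2 lost 74 of 75. Leaving out DKO ERY 1, 2 and 3 lost 37, 37 and 33 of 41, and leaving out either treated library, or DKO ERY 2 and 3 together, lost all 19.

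For Trp53KO and Bap1KO against WT, 25 of 51 list medians lay outside 95% of random lists, and 23 of 46 to 26 of 51 did under the alternatives. For these 25, the log2 ratio of summed UMIs under the alternatives stayed within the 95% interval of the reported value in 9 results and left it with the same sign in 55, and the sign changed in 6. That interval covers counting error only. The other list medians were not followed. In erythroid-like cells alone, the log2 ratio became 0.64 for monocyte, −0.23 for basophil and mast cell and 0.55 for MHC class II genes in Trp53KO, and 0.47 for monocyte and 0.74 for MHC class II genes in Bap1KO. In Bap1KO, late erythroid genes became −0.21 with stricter cell filters.

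The real grouping of the 6 DKO ERY and reference libraries is 1 of 10 splits, too few for a share under 0.05. It gave 122 genes against 0 at most in any other split over all kept cells (1 split as large), 46 against 0 within granulocyte-monocyte-like cells (1 split), and 0 against 17 within erythroid-like cells (10 splits as large), where the 17 came from WT with DKO ERY 1 and 2 against the rest, which points to structure among the libraries.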

Other observations

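All tests in this part were chosen after the result was seen.

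The cells named B-lineage-like followed the Bap1 label. They made up 7.79% of kept cells in WT (95% Clopper-Pearson interval 6.97% to 8.68%) and 8.95% in Trp53KO (7.999% to 9.98%), but 0.321% in Bap1KO (0.166% to 0.560%) and 0.639% ± 0.496 (SD, n = 8) over the 8 libraries labelled with a Bap1 deletion, the highest of which reached 1.51%. The Bap1 deletion is a candidate explanation, with an exact two-sided permutation p of 0.0222 over 45 arrangements and 0.2 after Benjamini-Hochberg adjustment over 9 classes. With 2 against 8 libraries no smaller p is possible, and a lone class at that p cannot fall below 0.2 after adjustment over 9 classes. The test could therefore not decide, and the explanation stays open. WT and Trp53KO are also 1 mouse each, and the labels give no age or disease stage. Unnamed clusters that scored highest for B lineage were not counted and did not all follow the label. A cluster topped by Dntt, with a close dendritic score, held 1.20% of WT, 2.24% of Trp53KO, 2.49% of Bap1KO and 0.748% to 2.37% of the DKO libraries. A low-depth cluster with Igkc, Ms4a1 and Bank1 held 3.95%, 2.81%, 0.963% and 0.102% to 1.26%. Dendritic-like cells were 6.05% ± 0.966 (n = 2) of kept cells in treated DKO ERY, 2.33% ± 0.567 (n = 3) in untreated DKO ERY and 2.81% ± 0.671 (n = 2) in DKO AML.

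WT held the most late neutrophils. A cluster with the secondary granule genes Ngp, Camp, Ltf and S100a9 at its top made up 16.5% of WT cells and 10.3% of DKO AML 1, and 0.966% to 6.69% of the other libraries. A more mature cluster topped by Retnlg, Mmp8 and Mmp9 made up 5.40% of WT and 0.383% to 2.37% of the rest. The record describes the cells as sorted for Kit and against lineage markers.

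Several genes differed in steps between groups within granulocyte-monocyte-like cells. Ocel1 was at 47.8, 51.7 and 65.5 CPM in DKO ERY 1, 2 and 3 and at 15.2 to 29.5 CPM elsewhere. Borcs8, also on chromosome 8, was at 60.9, 71.8 and 79.4 CPM in DKO ERY and 25.8 to 44.9 CPM elsewhere. Mns1 was at 28.2 to 36.1 CPM in DKO ERY, 27.5 to 32.1 CPM in the reference libraries, 9.81 and 11.7 CPM in DKO AML and 11.5 and 12.7 CPM in treated DKO ERY. Over all kept cells, Lhfpl4 was at 240.8 and 269.7 CPM in treated DKO ERY, 82.1 in DKO AML 1, 69.8 in Bap1KO and 31.1 in Trp53KO, and at 1.38 or less elsewhere. Eif3j2 was at 55.8 CPM in Bap1KO, 45.6 in DKO AML 2 and 4.46 or less elsewhere. The ribosomal RNA fragment Gm42418 was at 172.8 CPM in DKO AML 2 and 3139 to 15486 CPM in the others, and the antibody genes Jchain and Igkc were highest in WT, at 156.0 and 934.7 CPM.

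A whole autosome gained or lost in most cells is excluded as a feature of the double-deletion libraries. Among 19 autosomes in 7 libraries, with at least 169 genes each, the largest absolute median log2 ratio to the mean of the reference libraries over all kept cells was 0.145 (chromosome 13, DKO AML 2), against 0.585 for 1 more copy in every cell. It was 0.137 in granulocyte-monocyte-like cells (chromosome 13, DKO AML 2), 0.0725 in HSC/MPP-like cells (chromosome 14, DKO AML 2) and 0.172 in erythroid-like cells (chromosome 1, DKO ERY 2). The treated libraries held too few erythroid-like cells for that last measure, and the other classes were not measured alone.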
